A study of Mus musculus with 15 samples.

How the data were processed

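The 15 libraries are RNA from whole mouse cerebella dissociated in the first days after birth. The labels give postnatal day 1 in 1 field and day 2 in another, and a lowest RNA integrity number of 7.5. The series' design text says that granule neuron progenitors were enriched on a density gradient, so other cells of the cerebellum can be present. Biotin-labelled product was hybridised to Affymetrix Mouse Gene 2.1 ST arrays, 1 array per library. Groups and replicate numbers were taken from the labels. The labels describe the Math1-Cre control as deleted for Gsk-3 beta only and the no-Cre control as intact, and the descriptions of both give 1 altered Gsk3a allele. For 1 no-Cre library, replicate 5, the description leaves out the Gsk3b genotype. They do not say whether the Gsk3a allele is a germline null. The labels describe each library as whole cerebella of 1 replicate and name no litter or day, so p-values measure the spread between these samples.

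The deposited values are log2 expression values, 1 per array row, and per the submitters' processing notes the authors used RMA, Partek 6.6 and genome build mm9. The order of these steps and their settings are not given in the sources used here. The values ran from 2.11 to 13.49. The array medians and interquartile ranges differed between arrays; RMA normalizes probes before it summarizes them, so summarized values need not share a distribution. They were used as deposited. A level near the lowest values is at background, where differences between genes and arrays can be compressed.

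Of 41345 rows, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none. Rows with 1 symbol were kept, of which 23328 matched the reference gene table of assembly GRCm38.p6 by gene identifier and 0 changed name. For the 1082 genes with more than 1 row, the row with the highest mean over all libraries stood for the gene. This left 22180 genes, 1394 of them olfactory or vomeronasal receptor genes. The row annotated to Gsk3a carries a further symbol, 9130221H12Rik, a transcript within Gsk3a in that assembly, so it is outside the tested genes and is given as a row. No coordinates are printed, because the table's assembly differs from the build named in the notes.

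One limma model with a mean per group was fitted to all 15 libraries, with 12 residual degrees of freedom, no covariates and eBayes moderation. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes within each comparison, with a threshold of 0.05. The 24 gene lists held 317 memberships, of which 290 were measured. They were tested with camera at a preset correlation of 0.01 and adjusted over 72 tests, with camera at an estimated correlation and fry as alternatives. Some genes stand in more than 1 list. The genes named were set by a rule: Gsk3a, Gsk3b and Atoh1, with Axin2, Lef1, Gli1, Ptch1, Mycn, Ccnd1, Ccnd2, Mki67, Cdkn1b, Neurod1 and Rbfox3, always; the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, passing over unnamed and noncoding transcripts; and up to 4 called members of each list. The groups, tests, lists, naming rule and the other settings named further on were fixed before the data were examined. Single values were compared by exact permutation over all splits of the libraries. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

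The fit without the 4 libraries whose Gsk3a row goes against their label left 11 libraries and 8 residual degrees of freedom. It was added after the data were seen. The split of Axin2, Lef1 and other WNT genes had been noticed first and the Gsk3a row was looked up next. The same naming rule was applied to it, with non-overlap taken over the libraries left. A principal component analysis, genes that correlate with Axin2 over the libraries and genes near Gsk3a and Gsk3b were also looked at and are not reported. The gene table and lists of the 11-library fit were seen before the tests of explanations were written. The array spread as a covariate, and the fits without the 4 arrays of narrowest spread, were also added after the data were seen. For other splits of the 11 libraries, a small share was at first to be read as excluding chance; after its value was seen it was read as deciding nothing, because these libraries were kept for following their labels. Shares for a labelled count of 0 were also read as deciding nothing, after their values were seen, because every split reaches 0. For the receptor genes, a loss of over 50% of the calls with array spread as a covariate was at first to be enough for spread as an explanation; after the values were seen, their median difference had to fall by over 50% too.

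The other settings were a filter at the 30th percentile of mean level, quantile normalization, centring on the median, eBayes with trend and robust moderation, only the groups compared, array weights, the replicate number as a block, the code cg1724 that the 3 replicate-5 libraries carry as a block or left out, Xist as a covariate, the mean of a gene's rows, a 1.5-fold minimum, an adjusted p of 0.01, and leaving out each library.

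The model was tested on simulated data on the same 22180 genes, with 1 draw for each set of libraries. Each gene was drawn separately from a normal distribution with its own residual spread. The draws held no differences shared by a whole array and no libraries that go against their label. The shares that follow hold for such data and do not measure recovery in the real arrays. Over 15 libraries, for DKO against the no-Cre control, 58% of genes changed by 0.5 log2 were recovered, 96% at 1, 98% at 2 and 100% at 3, with 13 unchanged genes called. For DKO against the Math1-Cre control these were 60%, 96%, 98% and 100%, with 4 unchanged genes called. Over 11 libraries they were 32%, 94%, 96% and 100% against the no-Cre control and 24%, 86%, 96% and 100% against the Math1-Cre control, with 10 and 7 unchanged genes called.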

Results

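RNA from the cerebella of newborn mice was measured on 15 whole-transcript arrays, 1 per library. The labels form 3 groups of 5 libraries. In the double knockout (DKO), both isoforms of glycogen synthase kinase 3, Gsk-3 alpha and Gsk-3 beta, are deleted in progenitors of cerebellar granule neurons. In the Math1-Cre control only Gsk-3 beta is deleted, by a Cre recombinase expressed from the Math1 (Atoh1) promoter. In the no-Cre control the kinases are described as intact. The descriptions of both controls give the same Gsk3a genotype, with 1 altered allele. Each library is whole cerebella of 1 replicate, and the number of arrays limits the precision of every value. The values are log2 expression, and differences are given on that scale with the standard error (SE) of the limma fit. Correlations between libraries over genes ranged from 0.981 to 0.997.

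The row annotated to Gsk3a, which the array shares with 9130221H12Rik, went against the label in 4 libraries. Its mean was 8.65 ± 0.72 (SD, n = 5) in the libraries labelled DKO, 8.95 ± 0.75 (n = 5) in those labelled Math1-Cre control and 9.50 ± 0.08 (n = 5) in those labelled no-Cre control. The libraries labelled DKO 1 and DKO 3 lay at 9.47 and 9.37, beside the no-Cre range of 9.42 to 9.59. The libraries labelled DKO 2, 4 and 5 lay at 8.22, 7.89 and 8.27. The libraries labelled Math1-Cre 1 and 2 lay at 8.25 and 8.03, and Math1-Cre 3, 4 and 5 at 9.48, 9.50 and 9.51. DKO minus no-Cre was -0.86 (two-sided exact permutation p = 0.0238), DKO minus Math1-Cre was -0.31 (exact permutation p = 0.468), and Math1-Cre minus no-Cre was -0.55 (exact permutation p = 0.167). Gsk3b did not separate the groups, with means of 10.78 ± 0.14, 10.78 ± 0.09 and 10.77 ± 0.10 (SD, n = 5 each). A row that averages over a transcript need not cover a deleted exon, so this level says nothing of the Gsk-3 beta deletion.

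Because of that row, each comparison below is followed by the same comparison without the libraries labelled DKO 1, DKO 3, Math1-Cre 1 and Math1-Cre 2. This alternative was chosen after the data were seen. Axin2, Lef1 and other WNT genes had first been noticed to split over the same libraries, so the WNT results on the 11 remaining libraries are not blind to the choice. Genes outside that list split the same way, such as Pmaip1, at 3.48 and 3.53 in DKO 1 and 3 and 7.29 and 7.17 in Math1-Cre 1 and 2. The calls of genes that follow this split, and the counts that hold them, are thus not blind either. No library was moved to another group. Over the 11 libraries the Gsk3a row was 8.13 ± 0.21 in DKO (SD, n = 3), 9.50 ± 0.02 in the Math1-Cre control (n = 3) and 9.50 ± 0.08 in the no-Cre control (n = 5). DKO minus no-Cre was -1.38 (exact permutation p = 0.0179, the smallest possible) and DKO minus Math1-Cre was -1.37 (exact permutation p = 0.1, also the smallest possible). These differences follow from how the libraries were chosen.

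**Figure D1:**
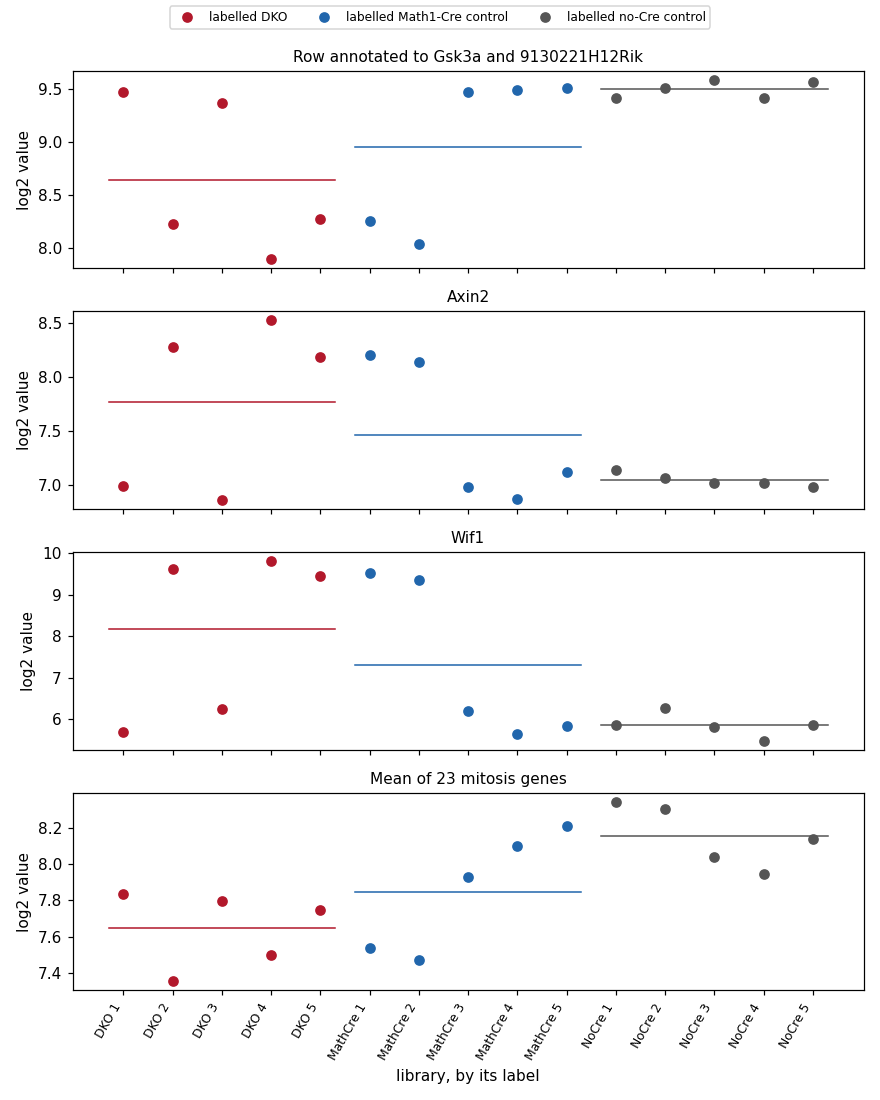
Log2 values per library, coloured by the group its label gives, with each group's mean as a line, for the row shared by Gsk3a and 9130221H12Rik, for Axin2, for Wif1 and for the mean of 23 mitosis genes. In the Gsk3a panel the libraries labelled DKO 1 and 3 lie at 9.47 and 9.37, beside the no-Cre libraries, and those labelled Math1-Cre 1 and 2 lie at 8.25 and 8.03.

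The comparison of DKO with the no-Cre control asks what Cre and the deletion of both kinases do together, against libraries described with 1 altered Gsk3a allele. In the libraries labelled DKO, the spindle genes Fam83d (-0.90 ± 0.12 SE, 1.86-fold lower), Ckap2 (-0.58 ± 0.09) and Spag5 (-0.52 ± 0.09) were lower than in the no-Cre libraries. The histone gene H2bc9 (-1.29 ± 0.20) and Rgs13, a regulator of G protein signalling (-1.05 ± 0.15), were lower too. The DKO mean of H2bc9 (4.01) lay at the receptor gene medians of these arrays (3.68 to 4.11), at background, so its difference can understate the change. She (-0.77 ± 0.13), Fam76a (-0.59 ± 0.10), the selenophosphate synthetase gene Sephs2 (-0.49 ± 0.07), Zbtb44 (-0.41 ± 0.07) and the actin nucleation factor gene Jmy (-0.40 ± 0.07) completed the named genes that fell. The olfactory receptor genes Olfr943 (+0.86 ± 0.12) and Olfr1495 (+0.65 ± 0.11) were the named genes that rose. In all, 16 of 22180 genes passed adjusted p 0.05 in limma, 4 higher and 12 lower, with 3862 at an unadjusted p under 0.05.

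WNT genes and progenitor genes did not pass for single genes in this comparison. Axin2, a negative feedback gene of WNT signalling, differed by +0.72 ± 0.33 (limma adjusted p = 0.273), and Lef1, a transcription factor of the pathway, by +1.05 ± 0.50 (adjusted p = 0.292). Atoh1, the transcription factor of granule neuron progenitors, differed by -0.71 ± 0.20 (adjusted p = 0.116). Neurod1 (-0.68 ± 0.13, adjusted p = 0.0611), Cdkn1b (-0.44 ± 0.10, adjusted p = 0.0772), Mycn (-0.52 ± 0.17, adjusted p = 0.159) and Mki67 (-0.43 ± 0.19, adjusted p = 0.266) did not pass either. Ccnd1 (-0.31), Gli1 (-0.15), Ptch1 (-0.08), Rbfox3 (-0.07) and Ccnd2 (-0.06) had adjusted p of 0.411 to 0.818.

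Among 24 gene lists fixed before the data were examined, camera placed the mitosis list (adjusted p = 1.12e-13), the replication list (adjusted p = 1.92e-08), the endothelial markers (adjusted p = 0.00689) and the glycogen metabolism list (adjusted p = 0.0287) lower in DKO than in the no-Cre control. The WNT list was higher (adjusted p = 0.00391). With an estimated correlation each of these had an adjusted p = 0.843. No member of them passed over all genes. Adjusted over the list alone, 20 of 23 mitosis genes, 14 of 22 replication genes, 1 of 11 glycogen genes and 0 of 10 endothelial markers were lower, and of 19 WNT genes 0 were higher and 1 lower. The WNT call ended without the library labelled DKO 4 (adjusted p = 0.0600), and the glycogen call without DKO 1 (0.0510), DKO 3 (0.127) or no-Cre 5 (0.0549). The glycogen call also ended with the low-value filter (0.161), after quantile normalization (0.0790) and with array spread as a covariate (0.273), the endothelial call with the filter (0.0557) and the covariate (0.216), and the WNT call without the 4 arrays of narrowest spread (0.137). Lists not called passed without single libraries: choroid plexus and ependymal markers without DKO 5 (0.00182), Math1-Cre 3 (0.0325), Math1-Cre 5 (0.0473), no-Cre 3 (0.0274) or no-Cre 5 (0.0362), pericyte and meningeal markers without DKO 5 (0.00837), oligodendrocyte markers without no-Cre 2 (0.0297), SHH/GLI genes without no-Cre 3 (0.0481) and interferon genes without no-Cre 5 (0.0458). The other lists had adjusted p of 0.0574 for choroid plexus and ependymal markers, 0.0799 for interferon, 0.124 for NRF2, 0.134 for oligodendrocyte, 0.142 for SHH/GLI and for microglia, 0.218 for pericyte and meningeal, 0.274 for p53 (lower by the test, with a mean of +0.02), 0.312 for CDK inhibitor, 0.314 for differentiating granule neuron and 0.342 for granule neuron progenitor genes. Notch, immediate early, GABAergic interneuron, unipolar brush cell and nuclei, and astrocyte lists had 0.655, glycolysis 0.844, Purkinje cell 0.952 and erythroid markers, of which 2 were measured, 0.973.

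Calls in this comparison rested on single libraries. The count was 0 without the library labelled DKO 3, no-Cre 1, no-Cre 2 or no-Cre 3, 4 without no-Cre 5, 6 without Math1-Cre 2, 7 without Math1-Cre 1 or 3, 8 without Math1-Cre 4, 9 without DKO 2, 32 without DKO 4, 191 without DKO 5 and 1546 without no-Cre 4. After quantile normalization no gene passed, and with the spread of the array as a covariate 2 did.

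In the 11 libraries, 9 of 19 WNT genes were higher in DKO than in the no-Cre control, those named next among them. Wif1, a secreted WNT inhibitor, was higher by 3.76 ± 0.17, Notum, which inactivates WNT proteins, by 2.57 ± 0.12, Lgr6, a receptor for R-spondins, by 2.54 ± 0.25, Lef1 by 1.92 ± 0.15 and Axin2 by 1.28 ± 0.10. The p53 target Pmaip1, which promotes apoptosis (+3.16 ± 0.24), the cell cycle inhibitor gene Cdkn1a (+1.23 ± 0.11) and the activin antagonist gene Fst (+2.39 ± 0.15) were higher, as were Mybpc1 (+2.84), Cryba2 (+2.54), Adam18 (+2.31), Esyt3 (+2.29) and the transcription factor gene Onecut1 (+2.24). The nicotinic receptor subunit genes Chrnb4 (-1.84 ± 0.21) and Chrna3 (-1.36 ± 0.14) were lower, with Rnf148, Mfap4 (-1.52), Cadps2 (-1.26), H4c17 (-1.24), H2bc9 (-1.22), the neuregulin receptor gene Erbb4 (-1.20), Nhlh1 (-1.20) and Rassf4 (-1.12). The no-Cre means of Notum (3.43), Cryba2 (3.51), Adam18 (3.60), Esyt3 (3.69) and Pmaip1 (3.81) lay near the receptor gene medians of the no-Cre libraries, at background. Those medians were 3.50 to 3.62, and 4.05 in no-Cre 4. The differences of these genes can thus understate the change. The same holds for the falls of H2bc9 and Rnf148, whose DKO means (4.08 and 4.30) lay near the receptor gene medians of DKO 2, 4 and 5 (3.70 to 4.01). In all 239 genes passed in limma, 97 higher and 142 lower, of which 11 also passed over all 15 libraries, with 2812 at an unadjusted p under 0.05. The balance turned with scaling, to 136 higher and 118 lower after quantile normalization and 146 higher and 83 lower after centring.

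Of 19 WNT genes 9 were higher and 0 lower over all genes, and 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.48e-25, and adjusted p = 0.00439 with an estimated correlation). Of 23 mitosis genes 9 were lower, and 23 adjusted over the list alone (camera adjusted p = 9.48e-25, but adjusted p = 0.420 with an estimated correlation). Kif11 (-0.89 ± 0.14), Bub1 (-0.79 ± 0.13), Aurka (-0.78 ± 0.16) and Cenpe (-0.76 ± 0.14), which act on the mitotic spindle or kinetochore, were the largest. Of 22 replication genes 3 were lower and 20 adjusted over the list alone, Mcm3 (-0.84), Cdc6 (-0.77) and Fen1 (-0.53, to a DKO mean of 3.63, at background) being the 3 (camera adjusted p = 8.06e-16, adjusted p = 0.612 with an estimated correlation). Of 12 progenitor genes 3 were lower, Nhlh1, Atoh1 (-0.80 ± 0.17, limma adjusted p = 0.0495) and Mycn (-0.64 ± 0.12), and 4 adjusted over the list alone (camera adjusted p = 0.00829, adjusted p = 0.996 with an estimated correlation). The progenitor call ended with the low-value filter (0.0581) and after quantile normalization (0.0850). The glycogen list was not called (camera adjusted p = 0.326). Interferon genes (camera adjusted p = 0.0459) and endothelial markers (camera adjusted p = 0.0341) were lower as lists with no member past the test over all genes, each with adjusted p = 0.996 with an estimated correlation. The endothelial call ended without the library labelled DKO 2 (0.267), DKO 4 (0.0907), no-Cre 1 (0.0956), no-Cre 2 (0.0565) or no-Cre 5 (0.0531), with the filter (0.147), after quantile normalization (0.121) and with array spread as a covariate (0.297). The interferon call ended without DKO 2 (0.247), DKO 4 (0.0820), no-Cre 2 (0.0749), no-Cre 3 (0.0786) or no-Cre 4 (0.157), with the filter (0.0997) and without the narrow arrays too (0.145). SHH/GLI genes passed without DKO 5 (0.0262) or no-Cre 3 (0.0233). The Notch target gene Hey1 (-0.74 ± 0.11) and the granule neuron gene Grin2c (-1.02 ± 0.17, to a DKO mean of 3.73, at background) were lower, and Gabra6, a receptor subunit gene of mature granule neurons, was higher (+1.70 ± 0.21, from a no-Cre mean of 3.70, near background). Second rows at lower signal did not show the change of Grin2c (+0.03) or Notum (+0.06), while that of Axin2 rose less (+0.44). Of 17 p53 targets 2 were higher, Pmaip1 and Cdkn1a, and the list was not called (camera adjusted p = 0.737). Mki67 (-0.64, adjusted p = 0.0980), Ccnd1 (-0.58, adjusted p = 0.0743), Neurod1 (-0.58, adjusted p = 0.0796) and Cdkn1b (-0.46, adjusted p = 0.103) did not pass.

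The count over the 11 libraries was 80 without the library labelled DKO 4, 108 without no-Cre 2, 131 without no-Cre 5, 135 without no-Cre 1 and 1060 without no-Cre 4. Wif1, Notum, Lgr6, Lef1, Axin2, Pmaip1, Cdkn1a and Fst passed whichever library was left out. Without DKO 4 each call named next was lost: Erbb4 (adjusted p = 0.0561) and Kif11 (0.0633) without that library alone, and Fen1 and Grin2c also without DKO 5 (0.0505 to 0.0715). Without DKO 2 also, Bub1 was lost (0.0608 to 0.0834), as were Mcm3 (also without no-Cre 2, 0.0814 to 0.155), Cenpe (also without no-Cre 2 or 5, 0.0581 to 0.130) and Mycn (also without Math1-Cre 4 or no-Cre 1, 2 or 5, 0.0506 to 0.111). H2bc9 was lost without DKO 2 or 4, Math1-Cre 5 or no-Cre 1, 2, 3 or 5 (0.0645 to 0.149), Cdc6 without DKO 2, 4 or 5, Math1-Cre 3 or no-Cre 1, 2 or 3 (0.0671 to 0.180) and H4c17 without these or no-Cre 5 (0.0703 to 0.193). Atoh1 (0.0610 to 0.129) and Aurka (0.0633 to 0.191) were lost without DKO 2 or 4, Math1-Cre 3, 4 or 5, or no-Cre 1, 2, 3 or 5.

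The comparison of DKO with the Math1-Cre control asks what the loss of Gsk-3 alpha adds to the loss of Gsk-3 beta. The genes named in this paragraph had to separate the labels in every library, also where the Gsk3a row went against the label. Pdk4, for example, lay at 5.64 and 5.48 in DKO 1 and 3 and at 6.88 and 6.82 in Math1-Cre 1 and 2. These genes thus follow the label and not the Gsk3a row, and need not show an effect of Gsk-3 alpha loss. The genes that fell in the libraries labelled DKO included Pdk4, an inhibitory kinase of pyruvate dehydrogenase (-0.95 ± 0.17, 1.93-fold), Cth, a cysteine synthesis enzyme (-0.81 ± 0.16), Glo1, which detoxifies methylglyoxal (-0.67 ± 0.14), the mitochondrial import gene Timm8a1 (-0.67 ± 0.14; -0.13 in each of its other rows) and the nucleoside diphosphate kinase gene Nme1 (-0.62 ± 0.12). Tc2n (-1.13 ± 0.22), H2bc9 (-0.95 ± 0.20), Fam83d (-0.65 ± 0.12), Lrrc74b (-0.64 ± 0.12) and the protease gene Corin (-0.61 ± 0.12) also fell. The DKO means of Corin (3.76), H2bc9 (4.01) and Timm8a1 (4.28) lay at or near background, so their differences can understate the change. The 10 named genes that rose were all olfactory or vomeronasal receptor genes, led by Olfr1431 (+1.07 ± 0.16), Vmn2r37 (+1.02 ± 0.18), Vmn2r44 (+0.97 ± 0.20) and Olfr1042 (+0.96 ± 0.16). Olfr943 (+0.74), Olfr1495 (+0.70), Olfr25 (+0.65), Olfr1176 (+0.59), Olfr1153 (+0.58) and Olfr168 (+0.57) were the others. In all 122 genes passed in limma, 29 higher, 16 of them receptor genes, and 93 lower, with 5091 at an unadjusted p under 0.05. The balance depended on scaling, with 11 higher and 9 lower after quantile normalization and 20 higher and 3 lower after centring.

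The spread of the arrays also differed between these groups, with interquartile ranges of 4.17 to 4.30 log2 in the libraries labelled DKO and 4.35 to 4.41 in Math1-Cre. The libraries labelled DKO 3, 4 and 5 and no-Cre 4 had the narrowest arrays, with interquartile ranges of 4.10 to 4.21 log2 against 4.30 to 4.44 in the other 11, and receptor gene medians of 3.97 to 4.11 against 3.50 to 3.70. The mean of the 16 called receptor genes was 3.99 to 4.35 in the libraries labelled DKO and 3.44 to 3.48 in Math1-Cre, and it was 3.90 in no-Cre 4 against 3.39 to 3.54 in the other no-Cre libraries. In DKO 1 and 2, whose arrays had ranges of 4.30, it was 3.99 and 4.01. With the spread as a covariate none of the 122 genes passed, and the median difference of the 16 was 0.45 against 0.59, with a median SE of 0.118 in both fits. After quantile normalization 5 of the 16 passed, with a median difference of 0.52 and a median SE of 0.102. The 4 narrowest arrays hold 3 DKO libraries, 1 no-Cre library and no Math1-Cre library, too few for a comparison within them. Among the other 11 arrays 613 genes passed, with DKO 1 and 2 as the only DKO libraries. Their ranges of 4.30 still lay below those of Math1-Cre, and the Gsk3a row of DKO 1 goes against its label.

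**Figure D2:**
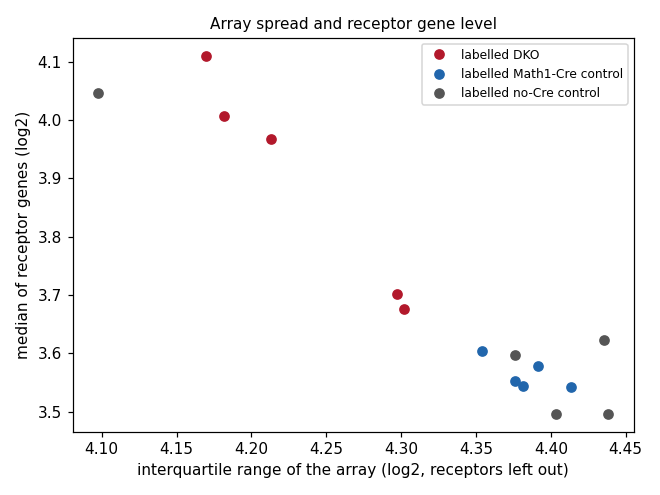
Median log2 value of the olfactory and vomeronasal receptor genes of each array against the interquartile range of its other genes, 1 point per library, coloured by label. The 4 arrays with ranges of 4.10 to 4.21, labelled DKO 3, 4 and 5 and no-Cre 4, have receptor medians of 3.97 to 4.11, and the other 11 arrays have 3.50 to 3.70.

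Axin2 (+0.30 ± 0.33, limma adjusted p = 0.596), Lef1 (+0.32 ± 0.50, adjusted p = 0.724), Atoh1 (-0.24 ± 0.20, adjusted p = 0.466), Mycn (-0.27, adjusted p = 0.363), Neurod1 (-0.38, adjusted p = 0.113) and Cdkn1b (-0.46 ± 0.10, adjusted p = 0.0521) did not pass between the libraries labelled DKO and Math1-Cre. Mki67 (-0.16), Ptch1 (-0.02), Ccnd2 (-0.01), Gli1 (+0.04), Rbfox3 (+0.04) and Ccnd1 (+0.05) had adjusted p of 0.630 to 0.980. Of the gene lists, the endothelial markers alone were called by camera, lower in DKO (adjusted p = 0.0480, adjusted p = 0.843 with an estimated correlation), with 1 of 10 lower adjusted over the list alone. Microglia and macrophage markers (adjusted p = 0.0574, 4 of 13 lower adjusted over the list alone), glycogen genes (adjusted p = 0.0574, 2 of 11 lower), oligodendrocyte markers (adjusted p = 0.0896, 3 of 9 lower) and choroid plexus and ependymal markers (adjusted p = 0.142, 0 of 7 lower) were not called. The endothelial call ended without the library labelled DKO 1 (0.0510), DKO 2 (0.106), DKO 3 (0.0844), DKO 4 (0.0565), Math1-Cre 5 (0.128) or no-Cre 1 (0.0514), with the low-value filter (0.205), after quantile normalization (0.179) and with array spread as a covariate (0.509). The WNT list (adjusted p = 0.330) passed without DKO 3 (0.0188), and the mitosis list (adjusted p = 0.0948) without DKO 1 (0.0415), DKO 3 (0.0188), DKO 5 (0.0495), Math1-Cre 1 (0.00287) or Math1-Cre 2 (0.000859). Glycogen genes passed without DKO 4 (0.0425), DKO 5 (0.0117), Math1-Cre 4 (0.0403), no-Cre 3 (0.0481) or no-Cre 4 (0.0483), and microglia markers without DKO 5 (0.0238), Math1-Cre 3 (0.0412) or Math1-Cre 4 (0.0113). Choroid plexus markers passed without DKO 5 (0.00837) or Math1-Cre 3 (0.0240), and oligodendrocyte markers without Math1-Cre 5 (0.00832). The count of genes was 0 without Math1-Cre 1, 1 without Math1-Cre 2 or 3, DKO 3, or no-Cre 2 or 3, 2 without Math1-Cre 4 or no-Cre 5, 4 without Math1-Cre 5, 17 without DKO 1, 32 without DKO 4, 39 without no-Cre 1, 80 without DKO 2, 402 without DKO 5 and 1288 without no-Cre 4.

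In these 11 libraries, 9 of 19 WNT genes were higher in DKO than in the Math1-Cre control, those named next among them. Wif1 was higher by 3.73 ± 0.19 (13.3-fold), Lgr6 by 2.61 ± 0.28, Notum by 2.55 ± 0.14, Lef1 by 1.87 ± 0.17 and Axin2 by 1.33 ± 0.11. Pmaip1 (+2.99 ± 0.27), Mybpc1 (+2.95), Cryba2 (+2.78), Fst (+2.46 ± 0.16), Adam18 (+2.38), Esyt3 (+2.32), Ascl4 (+2.13), Gabra6 (+1.73) and Cdkn1a (+1.19 ± 0.12) were higher. The Math1-Cre means of Cryba2 (3.27), Notum (3.45), Adam18 (3.52), Esyt3 (3.67), Gabra6 (3.67), Ascl4 (3.91) and Pmaip1 (3.98), and the DKO means of Grin2c (3.73) and Rnf148 (4.30), lay near background, so their differences can understate the change. Chrnb4 (-1.84 ± 0.23), Chrna3 (-1.36 ± 0.16), Mfap4 (-1.33), Nhlh1 (-1.17), Grin2c (-1.13), Rnf148 (-1.13), the kinetochore gene Spdl1 (-1.12), Rassf4 (-1.11), Cadps2 (-1.05), Stc1 (-0.99), Mycn (-0.70) and Hey1 (-0.67) were lower. In all 120 genes passed in limma, 64 higher and 56 lower, with 11 of them also called over the 15 libraries and 3518 at an unadjusted p under 0.05. Of 19 WNT genes 9 were higher, and 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.90e-23, adjusted p = 0.00439 with an estimated correlation). Of 23 mitosis genes 2 were lower, Kif11 (-0.86) and Mybl2 (-0.80, but +0.13 in a row near background), and 22 adjusted over the list alone (camera adjusted p = 2.29e-14, adjusted p = 0.804 with an estimated correlation). Of 22 replication genes 0 were lower, and 9 adjusted over the list alone (camera adjusted p = 6.81e-08, adjusted p = 0.996 with an estimated correlation). Endothelial markers were lower as a list (camera adjusted p = 0.0366, adjusted p = 0.996 with an estimated correlation), a call that ended without the library labelled DKO 2 (0.247), DKO 4 (0.0820) or Math1-Cre 5 (0.244), with the low-value filter (0.147), after quantile normalization (0.143) and with array spread as a covariate (0.322). Microglia markers passed without Math1-Cre 4 (0.0228) and pericyte and meningeal markers without Math1-Cre 5 (0.00522). Atoh1 (-0.65 ± 0.19, adjusted p = 0.165) did not pass. The count was 44 without the library labelled DKO 4, 47 without Math1-Cre 4, 53 without Math1-Cre 3, 74 without no-Cre 2, 76 without Math1-Cre 5 and 446 without no-Cre 4. Named calls lost without single libraries had adjusted p from 0.0503 to 0.170. Each was lost without DKO 4: Rassf4 also without Math1-Cre 3 (0.0655 to 0.0681), Adam18 without Math1-Cre 3 or 4 (0.0503 to 0.0998), Cadps2 without DKO 5 or Math1-Cre 3 or 4 (0.0503 to 0.0754), Grin2c without DKO 5 or Math1-Cre 4 or 5 (0.0574 to 0.114), Stc1 without DKO 2 or Math1-Cre 3, 4 or 5 (0.0581 to 0.116) and Rnf148 without DKO 5, Math1-Cre 3, 4 or 5 or no-Cre 2 (0.0505 to 0.124). Without DKO 2, Math1-Cre 4 or 5 or no-Cre 2 or 5, calls were also lost for Kif11 (0.0511 to 0.127), Mybl2 (0.0516 to 0.170), Mycn (0.0523 to 0.163) and Hey1 (0.0511 to 0.132). Further losses were of Kif11 without Math1-Cre 3 or no-Cre 1 or 3, Mybl2 without no-Cre 1 or 3, Mycn without DKO 5, Math1-Cre 3 or no-Cre 3, and Hey1 without DKO 5 or Math1-Cre 3.

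Genes changed the same way in DKO against both controls numbered 13 over the 15 libraries, 4 higher and 9 lower, among them Olfr943, Olfr1495, H2bc9 and Fam83d. Both comparisons share the DKO libraries. Simulated unchanged groups gave 0 such genes in each of 20 draws, independent lists would share 0.00523 higher and 0.0503 lower genes, and splits of the DKO libraries into separate parts gave a median of 0 and 0 to 16. The simulation drew each gene separately, without differences shared by a whole array, so a count near 0 was built in. Neither the simulated values nor the independent lists can tell an effect of the labels from such differences. The differences of the 2 comparisons correlated over genes at 0.810 against 0.498 simulated, with a covariance of 0.0363 against 0.00971; genes are not independent replicates. The count was 0 without the library labelled DKO 3, Math1-Cre 1, 2 or 4, or no-Cre 1, 2, 3 or 5, 1 without Math1-Cre 3, 2 without Math1-Cre 5, 6 without DKO 1, 7 without DKO 2, 123 without DKO 5 and 769 without no-Cre 4.

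Without the 4 libraries, 110 genes were shared, 61 higher and 49 lower, among them Wif1, Notum, Lgr6, Lef1, Axin2, Pmaip1, Cdkn1a, Chrnb4 and Chrna3. Simulation gave 0, again without differences shared by a whole array, so it decides nothing. Independent lists would share 0.280 higher and 0.359 lower genes. The 3 DKO libraries cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. The covariance was 0.0502 against 0.0156 simulated. The count was 42 without the library labelled DKO 4, 47 without Math1-Cre 4, 52 without Math1-Cre 3, 62 without no-Cre 2, 65 without Math1-Cre 5, 70 without no-Cre 5 and 377 without no-Cre 4.

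The comparison of the Math1-Cre control with the no-Cre control asks what Cre and the loss of Gsk-3 beta do together, since these libraries differ from no-Cre in both. No gene passed in limma over the 15 libraries or over the 11, with 716 and 488 genes at an unadjusted p under 0.05. Axin2 (+0.42 ± 0.33), Lef1 (+0.73 ± 0.50) and Atoh1 (-0.47 ± 0.20) each had an adjusted p of 1.00 over the 15 libraries. Mycn (-0.26), Ccnd1 (-0.36), Neurod1 (-0.29), Mki67 (-0.27), Gli1 (-0.19), Rbfox3 (-0.11), Ptch1 (-0.06), Ccnd2 (-0.06) and Cdkn1b (+0.01) had the same adjusted p. As lists, WNT genes were higher in the libraries labelled Math1-Cre (camera adjusted p = 0.0120), and progenitor (adjusted p = 6.72e-05), replication (adjusted p = 2.55e-16) and mitosis genes (adjusted p = 2.90e-19) were lower. Each had an adjusted p = 0.843 with an estimated correlation. Adjusted over the list alone, 1 of 22 replication genes was lower and no gene of the other 3 lists passed. The WNT call ended without the library labelled Math1-Cre 1 (0.254), Math1-Cre 2 (0.177) or no-Cre 1 (0.0589), and with the low-value filter (0.0594). SHH/GLI genes (adjusted p = 0.0574) passed, lower, without DKO 5 (0.0372), Math1-Cre 3 (0.0412), Math1-Cre 5 (0.00323), no-Cre 3 (0.0274) or no-Cre 4 (0.0365), with the filter (0.0499) and after quantile normalization (0.0321). Pericyte and meningeal markers (adjusted p = 0.124) passed without Math1-Cre 5 (2.53e-05).

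Over the 11 libraries, Axin2 (-0.05 ± 0.10), Lef1 (+0.04 ± 0.15) and Atoh1 (-0.14 ± 0.17) in the Math1-Cre control lay near their no-Cre levels, and the WNT list turned to lower without passing (camera adjusted p = 0.387). Math1-Cre 1 and 2, which were left out, had high Axin2 (8.20 and 8.14) and Lef1 (8.73 and 8.62). These WNT values thus follow from the choice of libraries and do not show what loss of Gsk-3 beta does. The progenitor list was not called (adjusted p = 0.0763). The mitosis (adjusted p = 0.000993), replication (adjusted p = 0.00177) and astrocyte lists (adjusted p = 0.0341) were lower by camera, each with adjusted p = 0.996 with an estimated correlation and no member past the test. Without the library labelled Math1-Cre 3, no-Cre 1 or no-Cre 2 the mitosis call ended (0.462, 0.0561 and 0.0565), as did the replication call (0.294, 0.107 and 0.0955). The astrocyte call ended without Math1-Cre 4 (0.271), Math1-Cre 5 (0.318), no-Cre 1 (0.122), no-Cre 3 (0.114) or no-Cre 5 (0.309). Progenitor genes passed without Math1-Cre 5 (0.0379), no-Cre 3 (0.00218) or no-Cre 4 (0.0379), with the filter (0.0404), after quantile normalization (0.0177) and with array spread as a covariate (0.0434). Without Math1-Cre 5, pericyte and meningeal (1.45e-05), choroid plexus (0.000132) and erythroid markers (0.00522) passed, without Math1-Cre 4 microglia markers (0.0159) and without no-Cre 3 unipolar brush cell and nuclei markers (0.0477).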

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

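The tests of the 4 libraries and of the receptor genes were chosen after their results were seen; the tests of the mitosis genes and of other splits of the libraries were set before theirs, except the range over left-out libraries and the reading of 3 shares of splits.

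In 14 of 309 groups of 5 libraries, 1 library lay far from the other 4. A rate of 1 in 20 gives 15.45, but the items are not independent and many are genes chosen by the naming rule. That number thus neither singles out nor dismisses any of these 14 groups. The library labelled no-Cre 4 lay apart in 6 of them: Glo1 at 9.17 against 9.44 to 9.53, Olfr1042 at 4.63 against 3.66 to 3.83, Vmn2r37 at 4.67 against 3.85 to 4.05, the array's interquartile range at 4.10 against 4.38 to 4.44, the receptor gene median at 4.05 against 3.50 to 3.62 and the mean of NRF2 targets at 7.52 against 7.82 to 7.88. The library labelled Math1-Cre 5 lay apart for Ccnd2 at 10.41 against 9.81 to 9.97, for the mean of unipolar brush cell and nuclei markers at 7.84 against 7.72 to 7.75 and for the mean of pericyte and meningeal markers at 8.26 against 7.16 to 7.48. Math1-Cre 2 lay apart for Ckap2 at 7.77 against 8.00 to 8.09. The library labelled DKO 2 lay apart for Atoh1 at 7.81 against 8.54 to 8.65, DKO 3 for the array median at 5.21 against 5.09 to 5.10, and DKO 5 for Olfr1153 at 3.96 against 3.40 to 3.51. No-Cre 1 lay apart for Rbfox3 at 9.42 against 9.15 to 9.20.

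In the libraries labelled DKO 1 and 3 and Math1-Cre 1 and 2, the Gsk3a row, Axin2 and Wif1 lay at the level of the other label. Of the 120 genes called between the remaining DKO and Math1-Cre libraries, 88.3%, 74.2%, 85.8% and 87.5% lay nearer the other label's mean in these 4 libraries, so an exchange of labels is a candidate explanation that stays open: the lowest share, 74.2%, fell just short of the bound set for it. After quantile normalization the Gsk3a row of 4 of the 4 libraries still lay nearer the other label. They were chosen by that row, so this count decides little. Array spread is argued against because arrays of like range differed in the row. At a range of 4.30 it was 9.47 in DKO 1 and 8.22 in DKO 2. At 4.38 it was 8.03 in Math1-Cre 2 and 9.50 in Math1-Cre 4. At 4.17 and 4.18 it was 9.37 in DKO 3 and 8.27 in DKO 5. Loss of Gsk-3 beta alone in the 2 Math1-Cre libraries is argued against too. Their higher Gsk3a row, the row that chose them, lay -1.17 log2 from the lowest remaining control. A failed deletion in the 2 DKO libraries cannot be told apart from the rest: their lower Gsk3a row lay -0.053 log2 from that control, and the labels do not say whether the Gsk3a allele is a germline null. Math1-Cre 1 was also the only library with both Xist (11.96) and Y chromosome genes such as Eif2s3y (9.03) high. How that bears on its label was not tested.

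The receptor genes that were higher in the libraries labelled DKO than in Math1-Cre may come from the narrower spread of these arrays, which stays open. With that spread as a covariate 0 of the 16 receptor genes stayed called, and after quantile normalization 5 did. Their median difference went from 0.59 to 0.45 and 0.52, with a median SE of 0.118, 0.118 and 0.102. The genes passed in this comparison went from 122 to 0 and 20. With the covariate the difference shrank at an equal SE, while after quantile normalization both shrank. The difference left after quantile normalization goes against spread as the whole cause, but at background it excludes nothing, and the covariate cannot decide, since every DKO array had a narrower range, 4.17 to 4.30, than every Math1-Cre array, 4.35 to 4.41. The mean of the 16 genes was 3.90 in no-Cre 4, the narrowest array, against 3.39 to 3.54 in the other no-Cre libraries, although Olfr943 (3.71) and Olfr1495 (3.73) lay within their range there, and it was higher in the wider arrays of DKO 1 and 2 (3.99 and 4.01), for genes chosen as higher in DKO. Expression of these genes in the cerebella, the biological alternative, stays open. Their median level, 3.69, lay at percentile 26.1 of all genes, just above the bound set against it. It also lay within the receptor gene medians of 3.50 to 4.11 that are taken here as background, so the level cannot decide.

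Without the 4 libraries, the mean of the mitosis genes was lower in DKO than in the no-Cre control by -0.63 ± 0.14 log2 (SE, n = 3 and 5). A lower share of granule lineage cells is argued against as the whole cause. The mean of 7 measured pan-lineage transcription factors differed by -0.090 ± 0.079. With 2 standard errors it reached -0.247, short of the -0.314 set as a bound. That bound was taken from the mitosis difference, whose own error was not counted, so a lower share as part of the cause stays open. Array spread is argued against as the whole cause, because 86.6% of the difference was kept after quantile normalization, 80.6% to 89.5% when a library was left out. Loss of both kinases, litter and day stay open, as does Cre as part of the cause, and how many progenitors divide was not tested. Cre as the whole cause is argued against in the libraries kept, since DKO and Math1-Cre both carry it. There the mitosis mean differed by -0.55 for DKO minus Math1-Cre and by -0.08 for Math1-Cre minus no-Cre. It was 7.35 to 7.75 in DKO and 7.93 to 8.21 in Math1-Cre. Math1-Cre 1 and 2, left out for their Gsk3a row, lay at 7.53 and 7.47, so these values depend on that choice.

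Other splits of the libraries bear on the counts. For DKO against the no-Cre control, 8 of 100 splits called as many genes as the 16 of the labelled split, so chance cannot be excluded, and the highest, DKO 1, 3, 4 and 5 with no-Cre 4 against the rest, called 1906, which points to a structure of the samples that includes the narrow arrays. For DKO against the Math1-Cre control, 2 of 100 splits reached the 122, the labelled one among them, a share under 0.05. The highest other, DKO 1 and 3 with Math1-Cre 3, 4 and 5, called 302, a split that follows the Gsk3a row. The labels also divide these arrays by their interquartile range, 4.17 to 4.30 in DKO and 4.35 to 4.41 in Math1-Cre. The share argues against a random division of these arrays but cannot tell the label from array spread. For Math1-Cre against no-Cre, 100 of 100 splits reached the 0 of the labelled split and the highest other called 1; every split reaches a count of 0, so this decides nothing. Without the 4 libraries, 2 of 56 splits reached the 239 for DKO against no-Cre, and the highest other, which set DKO 4 and 5 and no-Cre 4 against the rest, called 2898. As libraries were kept there for following their labels, that share does not exclude chance, a reading set after the value was seen. For DKO against Math1-Cre the 10 splits are too few for a share under 0.05: the labelled split called 120 and the highest other 0, and 1 split reached it. For Math1-Cre against no-Cre 56 of 56 splits reached 0, and the highest other called 11, which decides nothing either.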

How the results depend on the processing

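The fits without the 4 libraries, with array spread as a covariate and without the narrow arrays were chosen after the data were seen; the other tests on all 15 libraries were planned. Counts are given for DKO against no-Cre, DKO against Math1-Cre and both, in that order, beside 16, 122 and 13. They were 0, 20 and 0 after quantile normalization, 6, 23 and 3 after centring, 33, 236 and 23 with trend and robust moderation, 739, 773 and 350 with array weights, 9, 1 and 0 with Xist as a covariate, 9, 34 and 7 with a 1.5-fold minimum, 0, 1 and 0 at an adjusted p of 0.01, 2, 1 and 0 without the 3 cg1724 libraries, 2, 0 and 0 with array spread as a covariate, and 804, 613 and 474 without the 4 narrow arrays. Without the narrow arrays, DKO 1 and 2 were the only DKO libraries left. With only the groups compared, the first and last counts were 2 and 0. With cg1724 as a block they were 7 and 6. Without the 4 libraries they were 239 and 110. Fewer libraries or a stricter threshold lowers some counts by construction; otherwise the cause was not tested. Leaving out 1 library gave 0 to 1546, 0 to 1288 and 0 to 769. Math1-Cre against no-Cre stayed at 0 in each setting. The low-value filter and the mean of a gene's rows moved none of the 3 counts by over 1.5 times.

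Over the 11 libraries, beside 239, 120 and 110, counts were 154, 63 and 60 with array spread as a covariate, 76, 45 and 42 at an adjusted p of 0.01 and 448, 191 and 184 also without the narrow arrays, where 1 DKO library is left and is assumed to vary like the others. Leaving out 1 library gave 80 to 1060, 44 to 446 and 42 to 377.

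Over all 15 libraries, leaving out 1 library gave Gsk3a row differences of -1.07 to -0.67 for DKO minus no-Cre, -0.54 without Math1-Cre 2 to -0.12 without DKO 4 for DKO minus Math1-Cre, and -0.69 to -0.32 without Math1-Cre 2 for Math1-Cre minus no-Cre, moves within 1 SD of the libraries but, for both differences that involve Math1-Cre, of over 1.5 times. Without the 3 cg1724 libraries DKO minus Math1-Cre was -0.076. Without the 4 libraries the differences were, in the same order, -1.38, -1.37 and -0.0090.

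Scaling moved the direction of calls. Of the DKO against Math1-Cre calls, 23.8% were higher as deposited, 55.0% after quantile normalization and 87.0% after centring; of the DKO against no-Cre calls, 25% and, after centring, 50%. Over the 11 libraries these were 53.3%, 71.0% and 79.9% against Math1-Cre and 40.6%, 53.5% and 63.8% against no-Cre. Centring moved the median difference of all genes from -0.05 to +0.09 against Math1-Cre and from -0.02 to +0.09 against no-Cre.

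Of 32 named calls, all 32 were lost without the library labelled DKO 3, no-Cre 2 or no-Cre 3, and with array spread as a covariate, 27 after quantile normalization, 19 without the 4 libraries and 0 without no-Cre 4, and none reversed. Of 63 named calls over the 11 libraries, 28 were lost with the replicate block, 23 without DKO 4, 20 with array spread as a covariate, 7 after quantile normalization and 0 without no-Cre 4, and none reversed. The WNT list between the Math1-Cre and no-Cre controls reversed to lower without the 4 libraries (camera adjusted p = 0.387), which removes the Math1-Cre libraries with high WNT genes. Of 10 list calls over the 15 libraries, 4 ended and 1 was gained with the low-value filter, 2 and 2 after quantile normalization, 3 and 3 with array spread as a covariate, 0 and 8 without the 3 cg1724 libraries, 1 and 8 without the narrow arrays and 3 and 6 without the 4 libraries. Of 13 over the 11 libraries, 4 ended and 1 was gained with the filter, 3 and 1 after quantile normalization, and 2 and 2 with array spread as a covariate. Camera with an estimated correlation ended all 10 and 11 of the 13, and fry, which tests whether a list moves on balance one way, ended all 10 and 10 of the 13.

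Replicate numbers showed no clear pairing over the 15 libraries: correlations of deviations between same-numbered libraries ran from -0.303 to 0.299, 6 of 15 over 0.1, and 3 libraries matched best with their own number. The deviations were from the means of the labelled groups. The DKO and Math1-Cre groups each mix libraries with a high and a low Gsk3a row, so these correlations cannot exclude pairing. Pairing was not tested on the 11 libraries. With the replicate block the counts were 6, 0 and 0 over 15 libraries and 42, 25 and 25 over 11. It ended 3 list calls between the Math1-Cre and no-Cre controls over the 11 libraries (mitosis 0.190, replication 0.303, astrocyte 0.0633) and added 3 calls over the 15. Genes near background, the receptor genes among them, limit what the arrays show.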

Other observations

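No test was run on the values in this part; they were looked at after the data were seen.

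Genes of monoaminergic brainstem neurons, a list written after the data were seen, varied widely between libraries of 1 group. The mean of 7 measured genes was 3.90 in the library labelled Math1-Cre 5 and 7.24 in Math1-Cre 3, 4.18 in no-Cre 2 and 7.28 in no-Cre 3, and 4.41 in DKO 3 and 6.11 in DKO 2. The serotonin transporter gene Slc6a4 ran from 3.42 in no-Cre 2 to 8.56 in no-Cre 3, Tph2, the enzyme of neuronal serotonin synthesis, from 3.13 in Math1-Cre 5 to 7.37 in no-Cre 3, and Dbh, the enzyme of noradrenaline synthesis, from 3.71 in no-Cre 4 to 8.09 in Math1-Cre 1.

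Xist, transcribed from the inactive X chromosome, and genes of the Y chromosome excluded each other in 14 libraries. In the library labelled Math1-Cre 1 both were high, with Xist at 11.96, Eif2s3y at 9.03, Kdm5d at 8.46 and Uty at 8.67. Xist was high, at 11.67 to 12.13, in DKO 1, 4 and 5, Math1-Cre 3, 4 and 5 and no-Cre 2, 3 and 4, and lay at 3.99 to 5.54 in DKO 2 and 3, Math1-Cre 2 and no-Cre 1 and 5.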
